A study of Mus musculus with 6 samples.

How the data were processed

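Per the labels' protocols, whole-exome sequencing was done on 6 brain tissues of 2 mice of a conditional knockout glioma model, with 1 normal tissue and 2 tumor tissues per mouse. The labels do not say which gene was knocked out, and the tissue codes in the tumor names (OB_R, OB_R_C, OB_L and Piri_L) are used as given because the labels do not spell them out. The labels' molecule field names RNA and a part of the protocol describes cDNA libraries, whereas the series is typed as genome variation and the calls lay largely in introns and between genes. For that reason the values were treated as calls on DNA and not on RNA. That they are exome calls was taken from the protocol, and the positions of the calls do not show it.

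Per the labels' protocols, reads were paired-end, were filtered for adaptors, undetermined bases and low quality, were aligned with BWA and processed with Samblaster. Somatic single nucleotide variants (SNVs) were called with muTect. BWA and the build GRCm38 are also named in the submitters' processing notes, and the versions of the tools are not given in the sources used here. Insertions, deletions and copy number changes, which the protocol also names, were not analysed here. Each of the 4 deposited tables holds the SNVs of 1 tumor against the normal tissue of the same mouse, annotated by the authors with gene, region, coding effect, segmental duplications, repeats and a database of known mouse variants. Per the file headers, each tissue column holds the reference and alternative read counts, the mean quality of the alternative bases, the depth and the fraction of alternative reads. All 625 calls had passed the caller's filter and were marked somatic, so sites that failed the filter, and reads of a tumor at sites called only in the other tumor, were not analysed here.

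The allele fraction was computed as alternative reads over the sum of alternative and reference reads, and matched the deposited fraction at all calls of each tumor within a tolerance of 0.001. The stated depth of the normal tissue differed from that sum at 60, 45, 56 and 41 calls of OB_R, OB_R_C, OB_L and Piri_L, and the sum was used throughout. Median tumor depth at the called sites was 24, 20.5, 25 and 21.5 reads, and median normal depth was 20, 22.5, 19 and 16 reads. The total depth of the libraries is not given in the sources used here. At such depths the intervals on single allele fractions are wide. Intervals cover counting error only, since reads are not independent molecules. Every normal column had at least 8 reference reads and at most 1 alternative read, which are properties of called sites.

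An SNV was called common to a pair of tumors when chromosome, position, reference and alternative base were identical. A site is called marked here when the tables place it in a segmental duplication or a repeat or give it an entry in the database of known mouse variants, and unmarked otherwise. Protein-altering SNVs were missense, stop-gain, stop-loss and splicing changes. Where several transcripts were listed, exon and protein change were taken from the transcript with the highest residue number. Coordinates are those of the deposited tables, in GRCm38.

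Counts were given exact Poisson 95% intervals and shares exact Clopper-Pearson 95% intervals. The counts of the 2 tumors of a mouse were compared by an exact two-sided binomial test. Shares were compared by Fisher's exact test, two-sided. Differences of medians were tested by two-sided permutation with 100000 resamples, or by exact permutation where a group had under 10 values. The 6 pyrimidine-based substitution classes were compared by a chi-square statistic with 100000 Monte Carlo tables and by Fisher's exact test per class. Tumor and normal reads at each SNV were compared by a one-sided Fisher's exact test. The SNVs had been called against these same normal reads. This test therefore grades the read support of a call and is not independent evidence that the change is somatic. Benjamini-Hochberg adjustment was applied within each family, and the threshold was 0.05. The SNVs of a tumor and its reads are not replicates of mice, so these tests compare the libraries of these 2 mice and not conditions.

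Tests, 8 gene lists and the rule for naming genes were also fixed in advance. Genes were named when they belonged to 1 of 6 lists holding 353 genes and carried a protein-altering SNV, when they were among the 10 highest by mean fraction with an SNV common to both tumors of a mouse, when they were among the 5 highest of a tumor by private fraction, when they carried a stop or splicing SNV, or when they were altered in both mice. Some genes that this rule takes are counted but not reported here. Predicted genes and multicopy families, such as olfactory and vomeronasal receptors, were counted but not named under the parts of the rule on fraction, stops and splicing, except where the text says that a gene was named after its values were seen. The planned tests against coding length per list and per chromosome were not run because no coding lengths were used here. A comparison with gene numbers in the RefSeq table of the same build, and with synonymous SNVs, was added after the values were seen.

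Other settings chosen before the data were examined were minimum tumor or normal depths of 20 reads, minimum fractions of 0.1 and 0.2, leaving out database sites, repeats and duplications, multicopy families or SNVs within 100 bases of each other, other definitions of sharing, and leaving out each tumor in turn. Restriction to unmarked sites, to an alternative base quality of at least 30, or to both was added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data. The exact median test called 92.2% of 500 shifted and 5.2% of unshifted simulated comparisons of 8 with 40 values. The spectrum test called 98% of 400 shifted and 5.25% of equal simulated spectra of 200 SNVs each. For the comparison of tumor with normal reads, 1000 sites were simulated at the real depths with a tumor fraction of 20% and none in normal, and 41.1% were called, against 0% where both tissues had that fraction.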

Results

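Exomes of 2 mice with glioma were compared, each with 2 tumor tissues and 1 normal brain tissue. Mouse P8772 contributed the tumors OB_R and OB_R_C and mouse P9808 the tumors OB_L and Piri_L, and each tumor was called against the normal tissue of its own mouse. The labels do not say whether OB_R_C was a second piece of the tumor OB_R or another tumor, which limits what the values common to both mean. The 4 lists held 625 calls at 534 distinct positions and alleles. Of the distinct SNVs, 211 were intergenic (39.5%), 202 intronic (37.8%), 60 exonic (11.2%) and 1 at a splice site. Coding changes are described first because the question the design poses is which genes were mutated in the tumors and which mutations the tumors of 1 mouse had in common.

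Among the genes of the glioma driver list, Fgfr1 and Atrx carried a protein-altering SNV. Fgfr1 encodes a fibroblast growth factor receptor tyrosine kinase. In OB_L its change K656E, in exon 14 at position 25572449 of chromosome 8, was read in 10 of 95 reads (10.5%, exact Clopper-Pearson 95% interval 5.16 to 18.5%) and in none of 76 normal reads (Fisher's exact adjusted p = 0.0192). The affected lysine lies in the kinase domain, and the same substitution is a known recurrent change of human FGFR1 in brain tumors. Atrx, an X-linked chromatin remodeler often lost in human gliomas, carried R887Q in exon 9 in OB_R, at position 105875573. It was read in 6 of 56 reads (10.7%, 4.03 to 21.9%) against none of 34 normal reads (Fisher's exact adjusted p = 0.129). Neither SNV was called in the other tumor of the mouse, whose reads at these positions were not analysed here.

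Of the list of receptor tyrosine kinase, RAS, PI3K and IGF1 signaling genes, Axl, Rictor and Rasgrf2 were altered. Axl, a receptor tyrosine kinase, carried A831D in exon 20 in Piri_L (chromosome 7, position 25758837), in 7 of 31 reads (22.6%, 9.59 to 41.1%) with a Fisher's exact adjusted p of 0.0419 against normal. Rictor, a subunit of mTOR complex 2, carried S1091R in exon 31 in OB_R_C (chromosome 15, position 6786521) in 3 of 43 reads. Rasgrf2, an exchange factor for Ras, carried A433V in exon 11 in OB_L (chromosome 13, position 91890679) in 3 of 33 reads. The adjusted p against normal was 0.117 for Rictor and 0.213 for Rasgrf2 by Fisher's exact test.

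No member of the lists of DNA damage response and repair genes, chromatin regulators or oligodendrocyte lineage genes carried a protein-altering SNV. Of the long coding genes, Ttn carried A15954T in OB_L, in 6 of 128 reads. In all, 6 genes of the 6 lists used for naming were altered, 2 in P8772 and 4 in P9808, among 44 altered gene symbols. For the 41 of these found among the protein-coding genes of the reference table, the number expected from gene number alone was 0.661 (exact two-sided binomial p = 4.86e-05), a comparison chosen after the values were seen that leaves coding length out of account. Synonymous SNVs fell in 18 genes, none in these lists, and the 6 of 44 did not differ from that count past the threshold (Fisher's exact p = 0.168). With a minimum allele fraction of 0.1 the number of list genes was 3, and without OB_L it was also 3.

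Protein-altering SNVs common to both tumors were seen in 2 genes of P8772 outside multicopy families. Ttk, a kinase of the spindle checkpoint, carried D77G in exon 3 (chromosome 9, position 83839293), in 4 of 45 reads of OB_R (8.89%, 2.48 to 21.2%) and in 17 of 48 reads of OB_R_C (35.4%, 22.2 to 50.5%). Etnk2, an ethanolamine kinase, carried P43S in exon 1 (chromosome 1, position 133363890), in 8 of 25 and 5 of 12 reads, at a site with a database entry and 9 normal reads. Against normal, the Fisher's exact adjusted p of Ttk was 0.129 in OB_R and 3.12e-05 in OB_R_C. That of Etnk2 was 0.132 in OB_R and 0.0961 in OB_R_C by the same test. A further 4 of the 6 common protein-altering SNVs of P8772 lay in multicopy families. They were named after their values were seen and were the stop-gain Y208X of Vmn1r73, G736S of Vmn2r73, E234K of Olfr640 and A120S of Olfr1463. In P9808 the only protein-altering SNV common to both tumors was P492L of Zfpm1, a cofactor of GATA factors, in exon 10 (chromosome 8, position 122335678). It was read in 7 of 31 reads of OB_L and 6 of 31 reads of Piri_L, with 19 normal reads. The Zfpm1 SNV passed the threshold against normal in neither tumor (Fisher's exact adjusted p = 0.0959 in OB_L and 0.133 in Piri_L). No gene carried a protein-altering SNV in both mice.

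Among changes called in 1 tumor only, those of the highest fraction differed from tumor to tumor. In OB_L, Trim34b carried R173C in 7 of 25 reads (28%, Fisher's exact adjusted p = 0.053 against normal), at a duplicated site with a database entry. Usp7, a deubiquitinase acting on Mdm2 and p53, carried E1054K in 12 of 43 reads (27.9%), and Gfap, the intermediate filament of astrocytes, carried V417D in 11 of 43 reads (25.6%). Their Fisher's exact adjusted p against normal was 0.00204 and 0.00331. Cdh23 D2283Y and Mocs1 L61F followed with 14.6% and 11.4%, and their adjusted p by Fisher's exact test was 0.144 and 0.182. In Piri_L, Samd1 carried G339D in 9 of 21 reads (42.9%, Fisher's exact adjusted p = 0.0263). Atl2, an atlastin of the endoplasmic reticulum, carried G550S in 14% of reads, and Speg had a splice-site SNV in 8.11%. In OB_R_C, Zfp653 carried E453D in 10 of 70 reads (14.3%, Fisher's exact adjusted p = 0.00753), and N4bp3 carried L232R in 5 of 28 reads with a mean alternative base quality of 19. Zfp729a G367R, at a duplicated site, was read in 8.89%. In OB_R, Plch2 S1083I was read in 3 of 16 reads and Cyp4b1 R438W, at a duplicated site with a database entry, in 4 of 67 reads. Their adjusted p against normal was 0.229 and 0.149 by Fisher's exact test. The SNVs of Atl2, Speg, N4bp3 and Zfp729a did not pass that threshold either. Of 27 distinct protein-altering SNVs outside multicopy families, 8 exceeded normal past the threshold in the tumor with the higher fraction.

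In P8772, 16 of 24 coding SNVs were protein-altering (66.7%, 44.7 to 84.4%), of which 15 were missense and 1, in Vmn1r73, a stop-gain. In P9808, 25 of 39 were protein-altering (64.1%, 47.2 to 78.8%), of which 23 were missense, 1 a stop-gain in the predicted gene Gm1587 and 1 a splicing SNV in Speg. Both stop-gain genes were named after their values were seen. No difference between mice was detected (Fisher's exact p = 1). The 5 comparisons between mice, between tumors of a mouse and between common and private SNVs all had an adjusted p of 1 by Fisher's exact test. Of the 41 distinct protein-altering SNVs, 14 lay in multicopy families.

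The tumors carried 153 (OB_R), 132 (OB_R_C), 180 (OB_L) and 160 (Piri_L) SNVs, with exact Poisson 95% intervals of 130 to 179, 110 to 157, 155 to 208 and 136 to 187. No difference in number was detected between the 2 tumors of a mouse (exact binomial p = 0.236 for P8772 and 0.303 for P9808). The mean was 142.5 in P8772 and 170 in P9808, a ratio of 1.19 (exact permutation p = 0.333, the smallest p that 2 tumors against 2 allow). Many calls rested on few reads, and between 41.7% and 48.5% of the calls of a tumor had at most 3 alternative reads. Median allele fractions were 17.6%, 25%, 20% and 21.2%. Segmental duplications held 51%, 41.7%, 41.1% and 42.5% of the calls, and unmarked sites numbered 29, 42, 57 and 51. Taken call by call, 107 of the 625 calls (17.1%, 14.2 to 20.3%), all selected against the same normal reads, exceeded them past the threshold of Fisher's exact test after adjustment within each tumor. At unmarked sites alone this share was 30.7%.

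Tumors of the same mouse had many SNVs in common and tumors of different mice few. In P8772, 43 of 242 SNVs were common to OB_R and OB_R_C (17.8%, 13.2 to 23.2%). Besides the coding changes above, they included a SNV in the 5' untranslated region of Mapkap1, another subunit of mTOR complex 2 (chromosome 2, position 34432061), and synonymous SNVs of Olfr559 and Ahnak. In P9808, 40 of 300 were common to OB_L and Piri_L (13.3%, 9.7 to 17.7%). The highest fractions among its unmarked common SNVs were in the 5' untranslated region of Grin2b, an NMDA receptor subunit (chromosome 6, position 136044310), with 19 of 32 and 20 of 31 reads. Intronic SNVs of Pcsk1, Miox, Appl2 and Sfi1 were also common to both tumors of P9808. These noncoding and synonymous examples were chosen after their values were seen.

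Over the 4 pairs of tumors of different mice, 10 of 1240 SNVs in the pairwise unions were common (0.806%, 0.387 to 1.48%), against 83 of 542 (15.3%) over the pairs of the same mouse (Fisher's exact p = 4.14e-34). The pairs share tumors and the tumors of a mouse share a normal tissue, so the test does not rest on independent pairs. Distinct SNVs called in both mice numbered 8, of which 7 were marked, and 2 of those were synonymous SNVs of Mcm7 and Catsperg2. At unmarked sites the common SNVs numbered 13 of 58 in P8772 (22.4%), 6 of 102 in P9808 (5.88%) and 1 of 357 between mice (0.28%), and the share within mice still exceeded that between mice (Fisher's exact p = 1.41e-09).

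**Figure D1:**
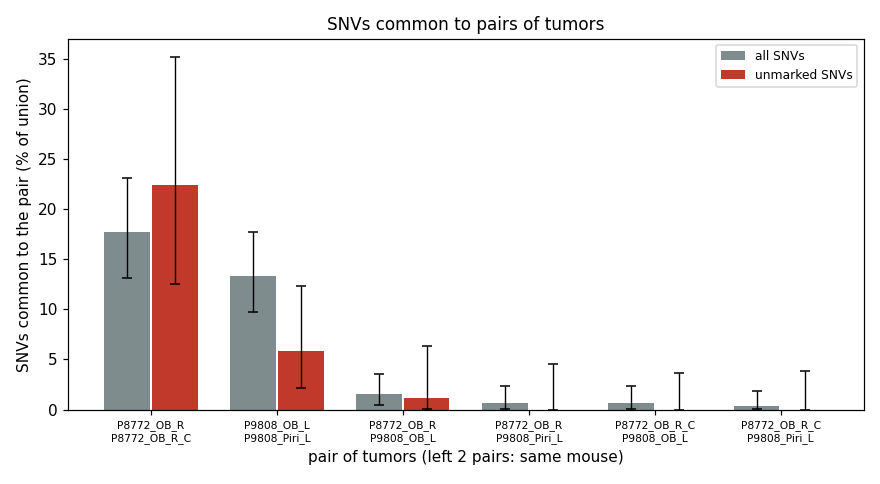
Share of SNVs common to each pair of tumors, in percent of the union of the pair, with bars for all SNVs (gray) and for unmarked SNVs (red) and exact Clopper-Pearson 95% intervals as error lines. The pairs of the same mouse stood at 17.8% and 13.3% of all SNVs, above every pair of different mice.

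SNVs common to both tumors had higher allele fractions than private ones in P9808. In OB_L the median fraction was 28.6% for common and 16.4% for private SNVs, a difference of 12.1 percentage points (permutation adjusted p = 0.00136). In Piri_L the medians were 27.9% and 18.2%, a difference of 9.74 points (permutation adjusted p = 0.00224). In P8772 the differences were -0.819 points in OB_R and 2.88 points in OB_R_C (permutation adjusted p = 0.888 and 0.499). The difference between mice was not tested. With a minimum normal depth of 20 reads the differences in P9808 were 0.232 and 5.77 points and did not pass the threshold. With a minimum tumor depth of 20 reads they were 3.53 and 5.89 points and did not pass it either. An SNV had to be called in both tumors to be common, which favors higher fractions. The common SNVs of P9808 were also shallower, with median depths of 14 and 17 reads against 25 and 21.5 over all calls of OB_L and Piri_L. The comparison cannot separate this selection from a property of the SNVs.

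The fractions of the common SNVs also differed between OB_R and OB_R_C. At the 13 unmarked common SNVs of P8772 the fraction in OB_R_C was a median of 2.67 times that in OB_R (range 0.533 to 4.34), and it was higher at 11 of them (exact binomial p = 0.0225). Outside multicopy families the median ratio was 2.15, and the fraction was higher at 6 of 8 (exact binomial p = 0.289). Examples were Vmn2r73 G736S, with 57 of 499 reads in OB_R and 109 of 344 in OB_R_C, and Ttk D77G. Ahnak and Sntg1 had the lower fraction in OB_R_C. At the 30 marked common SNVs, which were shallower, the median ratio was 1.12. It differed from that of the unmarked SNVs in a test that was not planned (permutation adjusted p = 0.00412). With at least 100 reads in both tumors the median ratio was 2.02 at 3 marked and 2.72 at 4 unmarked SNVs. These 4 unmarked SNVs all lay in multicopy families (Vmn1r73, Vmn2r73, Olfr559 and Olfr1463). In P9808 the ratio of Piri_L to OB_L was 0.972 at 6 unmarked and 1.09 at 34 marked common SNVs.

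**Figure D2:**
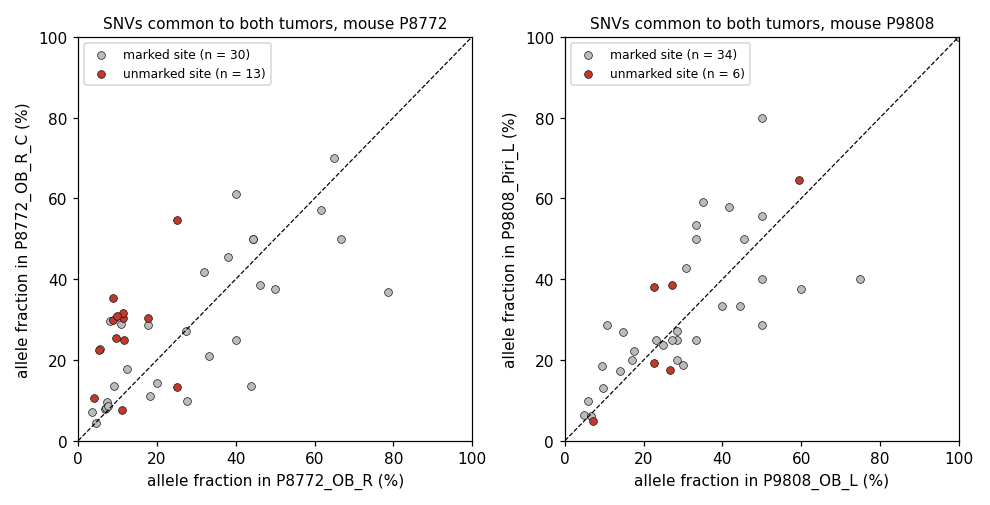
Allele fractions, in percent of reads, of the SNVs common to both tumors of P8772 (left) and of P9808 (right), with 1 point per SNV, red for unmarked and gray for marked sites, and a dashed line of equal fractions. In P8772, 11 of the 13 red points lie above the line, and in P9808 3 of 6.

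Over all SNVs, C>T was the most frequent substitution class in every tumor, whereas at the unmarked sites of Piri_L T>G (19 of 51) and C>A (14) were more frequent than C>T (13). It made up 37.6% of the SNVs of P8772 (91 of 242) and 27% of those of P9808 (81 of 300), and this class did not pass the threshold after adjustment (Fisher's exact adjusted p = 0.0562). At unmarked sites C>T made up 25.9% in P8772 and 29.4% in P9808. Over the 6 classes no difference between the mice was detected (chi-square Monte Carlo p = 0.149), although without OB_R_C the p was 0.0407. No difference between common and private SNVs was detected in P8772 (p = 0.284) or in P9808 (p = 0.648) by the chi-square Monte Carlo test over all sites. At unmarked sites the spectra of P8772 differed (13 common against 45 private SNVs, Monte Carlo permutation p = 0.0132, Cramer's V 0.486 against 0.161 over all sites), with T>G at none of the common and 14 of the private SNVs. With base quality of at least 30 as well, Cramer's V was 0.381 and the test did not pass the threshold (Monte Carlo permutation p = 0.326). Between tumors, unmarked T>G made up 19 of 51 SNVs of Piri_L and 5 of 57 of OB_L (Fisher's exact adjusted p = 0.00267), and 11 of 42 of OB_R_C and 3 of 29 of OB_R (Fisher's exact adjusted p = 0.801). With base quality of at least 30 as well, unmarked T>G made up 1 of 32 SNVs of Piri_L and 3 of 51 of OB_L, which did not differ past the threshold. The alternative bases of the unmarked T>G SNVs had a median quality of 21, against 37 for other unmarked SNVs.

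**Figure D3:**
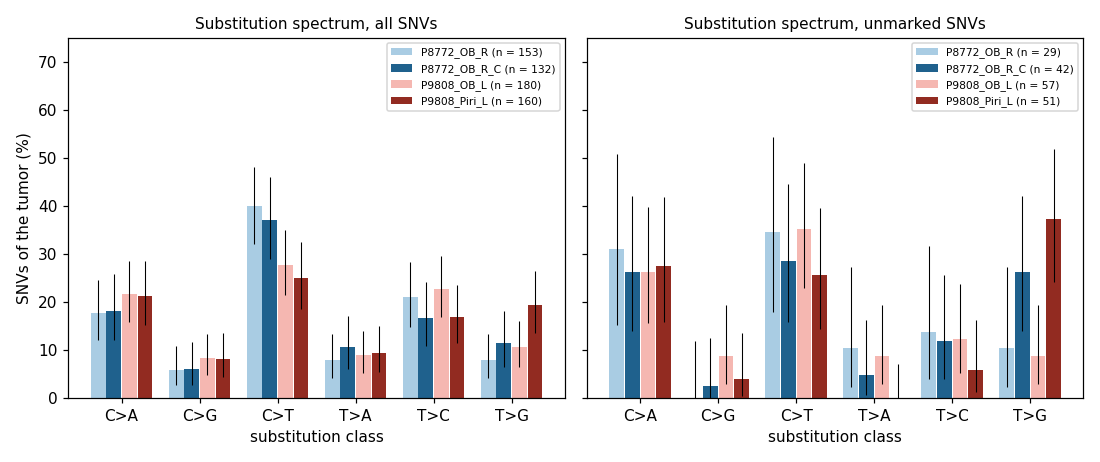
Share of each substitution class, in percent of the SNVs of a tumor, for all SNVs (left) and for unmarked SNVs (right), with 1 bar per tumor and exact Clopper-Pearson 95% intervals as lines. T>G made up 19.4% of all SNVs of Piri_L and 37.3% of its unmarked SNVs, with no limit on base quality.

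Over all sites, chromosome 4 held most SNVs of P8772 (27 of 242, 11.2%, 7.48 to 15.8%) and chromosome 1 most of P9808 (37 of 300, 12.3%, 8.83 to 16.6%). At unmarked sites chromosome 7 held most of P8772 (7 of 58), and chromosomes 1 and 11 held 11 of 102 each in P9808. These are counts without a test, since coding length per chromosome was not used here.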

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

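Except for the comparison of all SNVs within and between mice, the tests in this part were chosen after the results were seen, and the patterns are hypotheses found and tested on the same libraries. At unmarked sites the 2 tumors of P8772 had a larger share of SNVs in common (13 of 58) than those of P9808 (6 of 102), with a Fisher's exact p of 0.00395, which was 0.0681 outside multicopy families (8 of 46 against 6 of 94) and 0.00133 at base quality of at least 30 (13 of 41 against 6 of 77). The ratio of allele fractions between the 2 tumors at these SNVs was compared between the mice with an exact permutation p of 0.028 (0.0345 with the pair of P9808 turned), which was 0.0559 after adjustment over 4 comparisons of ratios and so did not pass the threshold. Base quality, which no planned comparison used, was below 30 at 33 of the 38 unmarked T>G SNVs and at 9 of the 141 other unmarked SNVs.

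The first pattern was the sharing of SNVs within a mouse. Errors called at the same sites in every library, whatever the normal reads, are argued against by the low sharing between mice (Fisher's exact p = 4.14e-34). Both tumors of a mouse were called against the same normal tissue, however, so a recurring error missed there can pass in both. The comparison does not exclude errors of that kind. Variants carried by the whole mouse and missed in its normal tissue, which both calls of a mouse share, also stay open. Given the pooled tumor fraction, as few alternative reads in normal had a probability under 0.0001 at 11 of 64 marked common SNVs (exact 95% interval of the share 8.9 to 28.7%), so shallow normal reads may account for most of them. At unmarked sites this was so at 9 of 19 (24.4 to 71.1%), among them Vmn2r73 (4.15e-37) and Ttk (5.97e-06). All called sites had at most 1 alternative read in normal, and the number of sites screened is not known. The probabilities are not corrected for that selection. They argue against such variants where they are lowest, as at Vmn2r73, and less so at Ttk. Vmn2r73, Olfr1463, Olfr559 and Vmn1r73, all among the 9, lie in multicopy families. The sharing itself does not tell descent of both tumors from a common mutated cell apart from such variants. Both predict the higher sharing within mice at unmarked sites with base quality of at least 30 (19 of 118 against 0 of 274, Fisher's exact p = 4.18e-11). It is also open whether OB_R and OB_R_C are pieces of 1 tumor. Outside the 9, fractions differed between the tumors at Mapkap1 and Olfr640 (Fisher's exact adjusted p = 0.0137 and 0.0319). The other unmarked common SNVs outside the 9 did not differ past the threshold. Whether this separates the explanations was not tested.

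The second pattern was the higher fraction in OB_R_C at unmarked common SNVs of P8772. A calling threshold in OB_R_C is argued against, since with the reads of both tumors mixed at each SNV, and OB_R_C held to at least 4 alternative reads and to its lowest unmarked fraction called (6.38%), the median ratio was 1.03 (95% of resamples 0.863 to 1.32) against the observed 2.67 (permutation p = 1e-05, the smallest the resamples can give), and 7 of the 13 SNVs were higher past the threshold of Fisher's exact test and none lower. Outside multicopy families the median ratio was 2.15, with 6 of 8 higher (exact binomial p = 0.289, with fewer SNVs tested). Of these 8, 3 were higher past the threshold and none lower, which were Ttk, Mapkap1 and an intergenic SNV on chromosome 5. Ttk and Mapkap1 lie outside the families by name alone, which does not test the placement of their reads. The families were defined by gene name, which an intergenic SNV lacks. Copies beyond the marked duplications and repeats were not looked for, so reads placed on the wrong copy stay open. A larger share of mutated cells in OB_R_C is a candidate explanation. The 11 of 13 SNVs that were higher (exact binomial p = 0.0225) are the pattern itself and do not test it. Of the 30 marked common SNVs, 4 passed the threshold of Fisher's exact test, and 3 of these were higher in OB_R_C. An intergenic SNV on chromosome 13 was lower there, with 7 of 71 reads against 26 of 94 in OB_R (Fisher's exact adjusted p = 0.0266). Copy number and tumor content were not analysed here.

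The third pattern was the number of T>G SNVs at unmarked sites. Base-calling errors are consistent with the lower quality of their alternative bases (permutation p = 1e-05, the smallest the resamples can give). A mutational process making T>G changes is argued against as the source of most of them, since T>G calls at marked sites had a median quality of 37 and were below 30 at 3 of 39, against a median of 21 at unmarked sites (permutation p = 1e-05). It stays open for the 5 unmarked T>G calls with a quality of at least 30. Quality was below 30 at 18 of 19 unmarked T>G calls in Piri_L and at 2 of 5 in OB_L.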

How the results depend on the processing

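Over 17 results, 130 planned and 51 added alternatives were run. Of these, 145 left the side of the threshold, or the value within its interval or 1.5 times the count, as reported. No direction turned where a test passed the threshold. Differences that were not called could change sign and still count among the 145. The protein-altering share of P9808 minus P8772, for example, was -2.56 points with the main settings and 5.81 points at a tumor depth of at least 20 reads. The alternatives on unmarked sites and base quality were chosen after seeing the data, and unless stated the cause of a change was not tested.

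The mean of 156 SNVs per tumor was 86.5 at a tumor depth of at least 20 reads, 75.8 at a normal depth of at least 20, 82.5 at a fraction of at least 0.2, 99.5 without database sites, 66.3 without repeats and duplications, 44.8 at unmarked sites and 34.3 at unmarked sites with base quality of at least 30, because calls were removed. Leaving out each tumor gave 148 to 164, and a ratio of P9808 to P8772 of 1.11 to 1.29.

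The common share of P8772 was 10.9% at a fraction of at least 0.2, 30.2% without repeats and duplications, 31.7% at unmarked sites with base quality of at least 30, 23.4% by gene and 32.6% over the smaller list. That of P9808 was 9.14% at a tumor and 7.59% at a normal depth of at least 20, 5.88% at unmarked sites, 7.79% with base quality of at least 30 as well, 19% by gene and 25% over the smaller list. The share between mice stayed below that within mice in 16 alternatives (highest Fisher's exact p = 1.41e-09), and was 0.498 to 1.1% with each tumor left out.

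The difference in fraction between common and private SNVs lost its call in OB_L and Piri_L at a tumor depth of at least 20 (3.53 and 5.89 points), a normal depth of at least 20 (0.232 and 5.77), unmarked sites (10.2 and 12.1) and unmarked sites with base quality of at least 30 (10.6 and 14.9), where fewer SNVs were tested. Cramer's V of the spectra between mice was 0.123, and the test passed the threshold at fractions of at least 0.1 (0.163) and 0.2 (0.204), with common SNVs counted in each tumor (0.143) and without OB_R_C, in a range of 0.112 to 0.164 over tumors left out. Common and private spectra of P8772 differed at unmarked sites (0.486), and with base quality of at least 30 as well (0.381) the test did not pass the threshold.

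The protein-altering share of P9808 minus P8772 ranged from -13.3 to 5.33 points with tumors left out, not called in any. The list genes numbered 3 at a fraction of at least 0.1 and 3 to 5 with tumors left out, 3 being without OB_L. Calls above normal made up 24.6% at a tumor depth of at least 20, 30.7% at unmarked sites and 33.6% with base quality of at least 30 as well. Chromosome shares stayed within their intervals, at 10.6 to 11.2% in P8772 and 11.1 to 12.5% in P9808 with tumors left out. Of single sites simulated at the real depths with a fraction of 20%, 41.1% were called. The simulation held that fraction at every depth, so it does not give the power for the real calls.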

Other observations

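Noncoding SNVs reached further genes of the fixed lists. An intronic SNV of Atrx was called in OB_R_C, besides the missense SNV of OB_R. Of the 230 genes named for noncoding SNVs, 5 belonged to the lists used for naming, which were Atrx, Hdac9, Grin2b, Cacna1c and Scn3a. The last 3 encode an NMDA receptor subunit, a calcium channel and a sodium channel. The Atrx intronic and Scn3a sites were marked, and the alternative bases at the Cacna1c site had a mean quality of 16. Outside the lists, a synonymous SNV of Hgf, the ligand of the Met receptor, was read in 9 of 114 reads of Piri_L (Fisher's exact adjusted p = 0.025 against normal). These genes were chosen after their values were seen.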
